A study of Drosophila melanogaster with 4 samples.

How the data were processed

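Ribosome footprints and poly(A) mRNA were measured in fly ovaries with and without NSUN2, with 1 library for each of the 4 combinations. Per the labels' protocols, ovary lysates were treated with micrococcal nuclease, single ribosomes were taken from a gradient, fragments of 28 to 30 nt were selected and ribosomal RNA was depleted before a small RNA library was made. Per the labels' protocols, the mRNA libraries came from poly(A) selected RNA with a kit that keeps strand. Micrococcal nuclease favours some bases over others when it cuts, which can move footprint values between genes, and selection of single ribosomes leaves out messages protected in larger complexes. The submitters' processing notes name cutadapt, TopHat2, HTSeq and the dm3 genome build, without versions or parameters. The treatment of reads that fit several places, the annotation, and the rule that chose the listed genes are not given in the sources used here.

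The deposited expression values are a signal per gene that was scaled to library depth and to a gene length, and the files do not name the scaling. It is TPM or a kind of FPKM, and not plain counts. The deposited m5C level is a fraction from 0.1 to 0.991, named in the file headers as the highest level of the gene, and it is identical in all 4 tables. The sample, the sites and the coverage behind the m5C fraction are not given in the sources used here, so its depth is unknown and it has no interval. Each table holds 2860 genes, so column totals are not library totals.

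The design fixed before the data were examined assumed read counts with trimmed mean scaling. The deposited tables hold scaled values, so the values as deposited were compared instead, as log2(value + 0.1), and a trimmed mean of log ratios was computed only as an alternative. A log2 difference on this scale understates the difference of genes with low values.

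Depth was sought in the values themselves. Within an assay, the ratio of a gene's values in the 2 libraries is a ratio of whole reads times 1 constant, found as 1.01 for footprints and 0.861 for mRNA. With ratios of whole numbers up to 100 and a relative tolerance of 1e-08, 1044 of 2857 genes in footprints and 134 of 2860 in mRNA came out whole. With a slightly moved constant, 0 and 0 did. Only constants near 1 were searched, and a constant wrong by a small whole factor also gives whole ratios. The check therefore cannot detect such a factor. A factor common to both reads is lost in the ratio and was restored from the rule that gene length is a whole number, which gave reads for 99.5% of genes in footprints and 98.5% in mRNA. The smallest factor was taken, so reads would be lower limits if the constant were right. In most of the genes named below, wild-type reads share a small whole factor that knockout reads lack. The constants are thus probably off by that factor, and wild-type reads are too high in most genes. Where a factor was missed, counting intervals are too wide and a gene can fall below a read minimum that its true reads would pass. Where wild-type reads are too high, counting intervals are too narrow and a gene can pass a minimum that its true reads would miss. The limit in the search for the length unit was chosen while the recovery was tested, after 2 lower limits gave unstable units. On simulated libraries the reads were exact for 86.8% of footprint genes and 80.3% of mRNA genes, too low for 12.7% and 18.6%, and too high for 0. The constant was found correctly there, so these shares do not cover a wrong constant. The length by which the footprint values were scaled came out of the same step, in a unit that the files do not give. It is called coding length on the assumption that this unit is the codon, and it is used only to order genes or as a ratio. Where the reads of a gene are too low, its length is too low by the same factor. A wrong constant can shift the lengths of some genes against others.

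Genes with a mean of at least 50 recovered reads over the 2 libraries of an assay were compared, and for translation efficiency the minimum held in both assays. A gene was called higher or lower if it differed at least 2-fold and its 95% counting interval excluded equality. Intervals are exact Clopper-Pearson intervals of the share of reads in one library, taken without the pseudocount, and for translation efficiency a sum of both assays' counting variances on the log scale. With 1 library per group no p-value was computed. Counting error alone was simulated 100 times per comparison from the recovered reads, so it is too small where wild-type reads are too high. On simulated libraries with 200 genes set apart, the rule called 100% of the 2.5-fold genes in mRNA, 98% in footprints and 98% in translation efficiency, and 0 unchanged genes in each. Correlations are across genes with 2000 bootstrap draws over genes, which show the spread between genes and not between animals.

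Groups of genes by m5C level were set beside 10000 random lists matched on mean mRNA value in 10 strata. The matching was tested on simulated lists of 442 genes among the 2492 genes of the translation efficiency comparison: 100 unchanged lists had a median percentile of 43.4, with 15 of them at or below percentile 10, and a list lowered by 0.1 on the log2 scale stood at percentile 0. A first run of 20 of these unchanged lists had given a median percentile of 25.7, after which their number was raised, so low percentiles are to be read with caution. The genes to be named were to be the targeted gene, the 8 highest and 8 lowest per comparison with at least 100 reads, and members of fixed gene lists. A RefSeq gene table of another assembly, used only for names, paired 18 of the 2860 identifiers with a symbol. The text therefore names those 18, chosen after the data were examined and not by value, and the 2 highest and 2 lowest identifiers in mRNA. No coordinates are given, because that table and the deposited values rest on different builds.

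Alternatives were scaling to the total reads of the listed genes, median of ratios, upper quartile and trimmed mean scalings. Others were read minimums of 10, 200 and none, a prior of 5 reads, a pseudocount of 1 and a 1.5-fold rule. The library with more recovered reads was also thinned. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.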

Results

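Ovaries of Drosophila melanogaster with the W1118 background were profiled in wild-type flies and in flies lacking NSUN2, an enzyme that methylates cytosine to 5-methylcytosine (m5C) in tRNAs and mRNAs. Each genotype had 1 ribosome footprint library and 1 poly(A) mRNA library, so the 4 libraries fell into 4 groups of 1, and no difference between genotypes has a replicate check. Ribosome footprints are the short mRNA fragments that a ribosome shields from nuclease, here 28 to 30 nt long, and their abundance follows how much a message is occupied by ribosomes. Values were given for the same 2860 genes in each library, together with the highest m5C level listed for each gene. The listed m5C levels ran from 0.1 to 0.991 with a median of 0.269, so every gene in the tables carried a listed m5C level of at least 0.1, and genes without one were not analysed here.

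Depth was recovered from the values as reads per gene. The wild-type footprint library had 2416826 recovered reads over the listed genes, with a median of 288 per gene. The knockout footprint library had 2303445, with a median of 275. The mRNA libraries had more recovered reads, with 10448917 in wild type and 8882019 in the knockout. In most of the genes named below, wild-type reads were multiples of 2 in footprints and of 3 in mRNA. Most of their knockout reads were not. Wild-type reads are therefore probably too high by these factors in most genes. The knockout libraries may be the deeper ones. The median deposited value was 30.1 in wild-type and 27.9 in knockout footprints, and 33.5 and 33.6 in the mRNA libraries. In footprints, 3 genes were listed at 0 in wild type and 1 in the knockout, while no gene was at 0 in mRNA. Counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and bootstrap intervals cover the spread between genes. Counting intervals and simulated counting error rest on the recovered reads, so both are probably too small for most genes.

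The first comparison asked which messages differed in abundance between the genotypes. The gene furthest below wild type in knockout mRNA was FBgn0026079, with a value of 25.2 in wild type and 1.17 in the knockout, 19.9-fold lower (95% counting interval 14.7 to 32.6). The next lowest, FBgn0030420, stood at 49.2 in wild type and 5.33 in the knockout, 9.08-fold lower (7.77 to 11.04). At the other end, FBgn0037203 had 7.33 in wild type and 116 in the knockout, 15.7-fold higher (14.2 to 17.8), and FBgn0015737 had 8.95 and 92.8, 10.3-fold higher (9.07 to 11.9). The tables give gene identifiers without names, and the gene table used here paired 18 of the 2860 identifiers with a symbol. The targeted gene was not among those 18. Whether FBgn0026079 or another listed identifier is the targeted gene was not determined, so no value here serves as a check of the knockout.

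Of 2837 genes with a mean of at least 50 mRNA reads, 49 were at least 2-fold higher in the knockout and 45 at least 2-fold lower, with counting intervals that excluded equality. Counting error alone, drawn from the recovered reads, gave 0 such genes in 100 simulated pairs of libraries. The median log2 difference was 0.00, or 0.05 with upper-quartile scaling, and the SD over genes was 0.44, against 0.07 in the simulated pairs. The difference between these libraries therefore exceeded counting error, and its spread between animals is unknown. With a pseudocount of 1 in place of 0.1, FBgn0026079 had a log2 mRNA difference of -3.59 against -4.31.

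The second comparison asked which messages differed in ribosome footprints. FBgn0026079 was again the lowest, with 38.8 in wild type and 1.28 in the knockout, 28.3-fold lower (18.8 to 52.6). With a pseudocount of 1 its log2 footprint difference was -4.13 against -4.82. FBgn0030420 was 5.75-fold lower in footprints (3.95 to 9.33), from 13.2 to 2.22. FBgn0037203 was 1.94-fold higher in footprints, from 18.3 to 35.5, and FBgn0015737 went the other way from its mRNA, from 45.4 to 24.2. Among 2512 genes with a mean of at least 50 footprint reads, 45 were at least 2-fold higher in the knockout and 117 at least 2-fold lower. Counting error drawn from the recovered reads gave a mean of 0.04 such genes and at most 1. Lower genes thus outnumbered higher ones at this size. The median log2 difference over all 2512 genes was -0.05, a shift whose sign turned under 3 of the 4 other scalings. Those 3 gave 55 or 56 genes higher and 93 to 98 lower, and upper-quartile scaling gave 43 and 119. Counting intervals lay above 0 in 27.5% of genes and below 0 in 34.2%, against 33.1% and 27.8% with the total reads of the listed genes as scaling. Intervals that are too narrow make these shares too high. The 4 other scalings move each footprint difference by -0.01 to 0.08 on the log2 scale. The SD over genes was 0.54, against 0.14 from counting error.

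Most genes that were lower in footprints did not differ as much in mRNA. Of the 113 genes at least 2-fold lower in footprints that also passed the mRNA read minimum, 6 were at least 2-fold lower in mRNA, and their median log2 mRNA difference was -0.02. Of the 45 higher in footprints, 5 were at least 2-fold higher in mRNA, and their median log2 mRNA difference was 0.12. Read in the other direction, 39 genes were at least 2-fold higher in knockout mRNA and passed the footprint read minimum. Their median log2 difference was 1.35 in mRNA and 0.10 in footprints, and 5 of the 39 were at least 2-fold higher in footprints. The 31 genes lower in mRNA had medians of -1.28 in mRNA and -0.22 in footprints, with 6 of the 31 at least 2-fold lower in both. Across 2492 genes, which are not independent replicates, the mRNA and footprint differences had a Spearman rho of 0.150 (95% bootstrap interval over genes 0.109 to 0.193) and a Pearson r of 0.175. With at least 200 reads required, rho was 0.107.

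**Figure D1:**
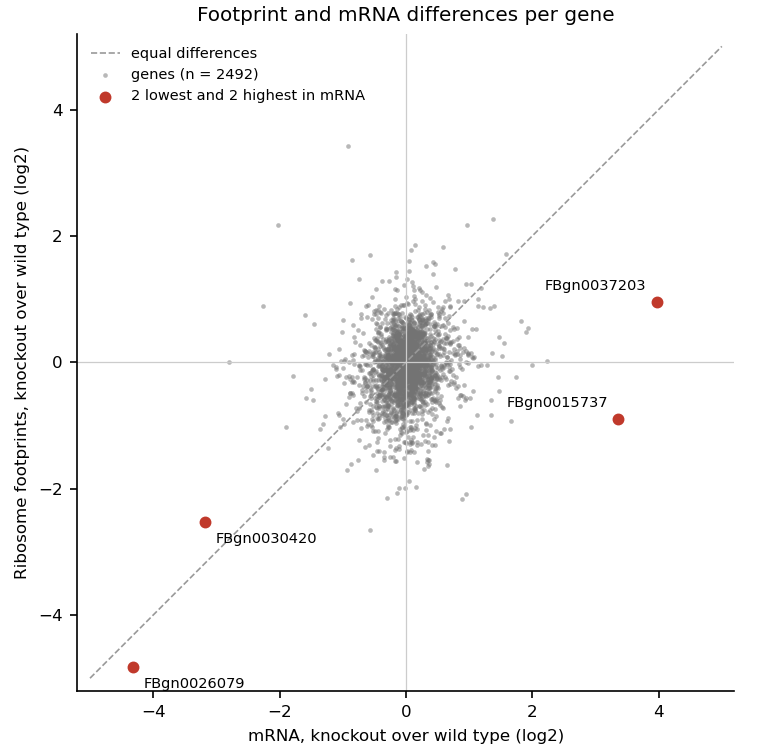
Difference between knockout and wild type in mRNA (x axis, log2) and in ribosome footprints (y axis, log2) for 2492 genes, 1 point per gene and 1 library per axis and genotype. The 2 lowest genes in mRNA lie near the dashed line of equal differences, FBgn0037203 and FBgn0015737 lie far below it, and rho over all points was 0.150.

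The third comparison set the footprint difference against the mRNA difference of the same gene, which gives the difference in translation efficiency, the footprint value per mRNA value. FBgn0015737 had the lowest translation efficiency relative to wild type of all 2492 genes, with a log2 difference of -4.26, and FBgn0037203 had -3.02. Both were named for their high knockout mRNA, which enters this ratio, and FBgn0037203 was itself higher in knockout footprints. FBgn0026079, low in both assays, had a log2 translation efficiency difference of -0.51 with a counting interval from -1.39 to 0.38, and FBgn0030420 had 0.66 with an interval from -0.01 to 1.27. Translation efficiency was at least 2-fold higher in the knockout for 77 genes and at least 2-fold lower for 151, against a mean of 0.15 and at most 2 from counting error. The median log2 difference was -0.06, and under the 4 other scalings it was 0.00 in 3 and -0.12 with the upper quartile. The footprint term was the larger part of the difference in 54 of the 77 higher genes and in 111 of the 151 lower ones. Of the 39 genes higher in mRNA, 24 were at least 2-fold lower in translation efficiency, and 16 of the 31 genes lower in mRNA were at least 2-fold higher. These last counts share the mRNA libraries on both sides, so a part of them follows from the ratio itself.

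Within each genotype, translation efficiency spanned a wide range. The 90th percentile of genes stood 15.2-fold above the 10th in wild type and 13.3-fold above it in the knockout. The ranking was close between genotypes, with a Spearman rho of 0.915 (0.904 to 0.924) across 2492 genes. Of the 249 genes with the highest translation efficiency in wild type, 185 were also in the same upper part of the ranking in the knockout, against 24.9 by chance. Of the 250 with the lowest, 181 were shared. Footprint and mRNA values had a rho of 0.512 across genes in wild type (0.479 to 0.543) and 0.575 in the knockout (0.547 to 0.601).

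The genes that could be named cover enzymes of metabolism, chromatin and transcription proteins, and signalling proteins, and were reported because they had a symbol, not for their values. Aldh, a mitochondrial aldehyde dehydrogenase, was the only one of the 18 at least 2-fold apart in mRNA. Its mRNA value was 77.04 in wild type and 159 in the knockout, 2.07-fold higher (2.001 to 2.14). That interval is probably too narrow, so its lower end does not place Aldh above 2-fold. Its footprint value was 364 in wild type and 526 in the knockout, 1.44-fold higher (1.38 to 1.51), so its log2 translation efficiency difference was -0.52 (-0.60 to -0.44). Meltrin, an ADAM-family metalloprotease, was 1.41-fold higher in mRNA (1.28 to 1.57) and 1.20-fold lower in footprints, with a log2 translation efficiency difference of -0.76 (-1.03 to -0.51). Treh, the enzyme that splits trehalose, the main blood sugar of insects, was 1.24-fold higher in mRNA (1.17 to 1.31) and 1.16-fold higher in footprints (1.00 to 1.33). Mal-B2, a maltase, had counting intervals that held 0 in all 3 comparisons. Mccc2, a carboxylase subunit of leucine breakdown, had a log2 footprint difference of -0.45 (-0.88 to -0.04) with a log2 mRNA difference of -0.02. Under 3 of the 4 other scalings the footprint intervals of Mccc2 and Meltrin held 0, and with the upper quartile that of Treh did.

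Among the chromatin and transcription genes, Mau2, which helps load cohesin onto DNA, was 1.20-fold higher in mRNA and had a log2 translation efficiency difference of -0.58 (-0.93 to -0.22). MED1, a subunit of the Mediator complex, had -0.44 (-0.72 to -0.15), and pps had -0.24 (-0.41 to -0.07). Asx, a Polycomb-group gene, was 1.30-fold lower in mRNA. It was below the minimum of recovered footprint reads, which can be too low, so it was left out of the other comparisons. The ubiquitin ligase gene Herc4 was 2.01-fold lower in footprints, resting on at least 28 reads in wild type and at least 14 in the knockout, lower limits that lie below the read minimum. The gene snama, which encodes an RBBP6-like protein, was the only named gene whose translation efficiency interval lay above 0, at 0.18 (0.05 to 0.30), and with upper-quartile scaling its interval held 0. AMPKalpha, the catalytic subunit of an energy-sensing kinase, had a log2 mRNA difference of 0.01 (-0.06 to 0.08) and a log2 translation efficiency difference of 0.16 (-0.08 to 0.40). The interval of translation efficiency also held 0 for Vps15, a subunit of a lipid kinase complex, for the Rab regulator GAPcenA, for the cytochrome c oxidase assembly factor Coa7, and for CG7091 and CG42271. CG8516 had the lowest value of the named genes, -0.90 (-1.39 to -0.42).

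No named gene was 2-fold apart in footprints or translation efficiency among the 16 at or above the minimum of recovered reads. Of these 16 the counting interval of translation efficiency lay below 0 in 7 and above 0 in 1. Over all 2492 genes it lay below 0 in 35.6% and above 0 in 27.0%, shares that are too high where intervals are too narrow. With the total reads of the listed genes as scaling these shares were 31.7% and 30.4%, and 6 named genes lay below 0, without Mccc2. With the upper quartile the shares were 39.8% and 23.4%, with 7 named genes below 0 and 0 above. The 18 genes are a small and arbitrary part of the tables and stand for no pathway. The gene lists fixed before the data were examined, and the comparison by codon, were not analysed here because they need names or coding sequences for the remaining identifiers.

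**Figure D2:**
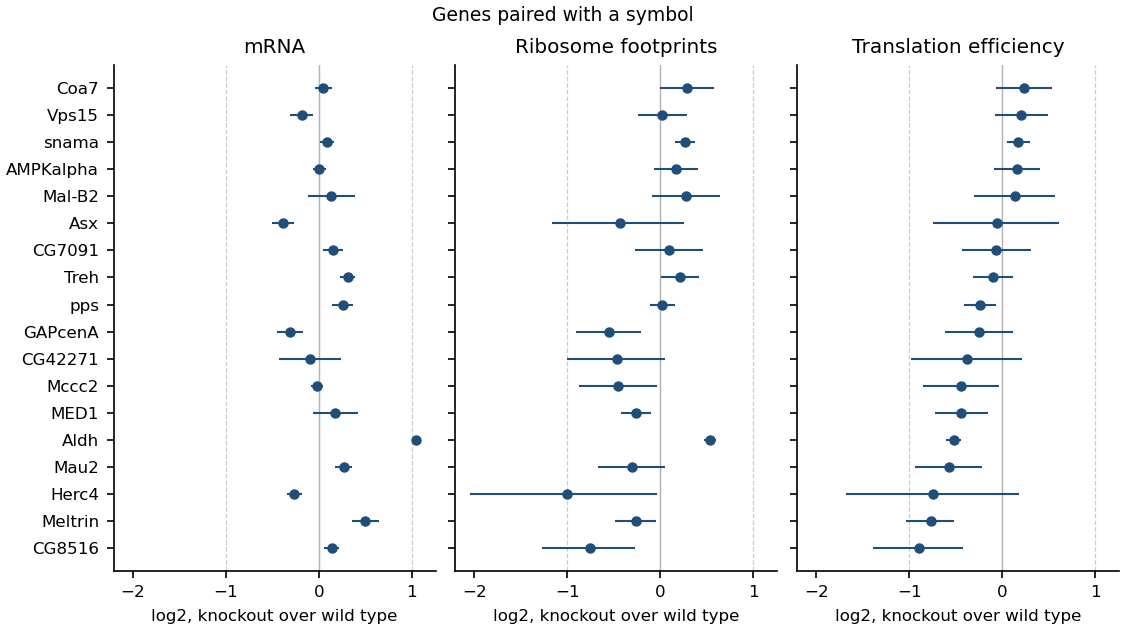
Log2 difference between knockout and wild type in mRNA, ribosome footprints and translation efficiency for the 18 genes with a symbol, ordered by translation efficiency. Points are values from 1 library per group, bars are 95% counting intervals from recovered reads, and dashed lines mark 2-fold. Aldh in mRNA is the only point past 2-fold at or above the minimum of recovered reads. Herc4 in footprints, with 28 and 14 recovered reads that may be too low, lies below that minimum. Other scalings move all points of a panel alike.

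The last comparison asked whether genes with higher listed m5C levels differed more between the genotypes. The genes were divided at m5C levels of 0.2, 0.4 and 0.6, edges chosen after the data were seen. The 892 genes from 0.1 to 0.2 had a median log2 translation efficiency difference of -0.02 (95% bootstrap interval -0.06 to 0.02). The 768 genes from 0.2 to 0.4 had -0.05, the 387 genes from 0.4 to 0.6 had -0.14 (-0.18 to -0.05), and the 445 genes at 0.6 and above had -0.12 (-0.19 to -0.07). The other scalings move all groups by 1 amount. Under 3 of them the 2 groups of lower m5C level were above 0, at most 0.04 and 0.02, and the upper groups were at -0.08 and -0.05 at the highest. With the upper quartile, the 4 medians were -0.08, -0.10, -0.20 and -0.17. Among 10000 random lists of the same size matched on mRNA level, these medians stood at percentiles 94.3, 79.7, 2.69 and 10.6. In mRNA the 4 medians were 0.01, -0.00, 0.02 and 0.03, and in footprints 0.00, -0.05, -0.09 and -0.08.

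Gene by gene, the m5C level had a rho of -0.054 with the translation efficiency difference (-0.094 to -0.014), of -0.076 with the footprint difference (-0.116 to -0.039) and of -0.013 with the mRNA difference (-0.053 to 0.026). The genes with higher m5C levels were also longer, with a rho of 0.162 between m5C level and the length by which footprints were scaled. They had less mRNA, with a rho of -0.120. The level is the highest of a gene, so a longer gene can have more places for a high one. Which of the levels depend on NSUN2 is not given. With lengths and mRNA level taken out, the rho of m5C level with the translation efficiency difference was -0.012 (-0.053 to 0.025). The genes at least 2-fold higher and those at least 2-fold lower in translation efficiency had median m5C levels of 0.279 and 0.278. In wild type alone, m5C level and translation efficiency had a rho of 0.020 (-0.019 to 0.060).

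**Figure D3:**
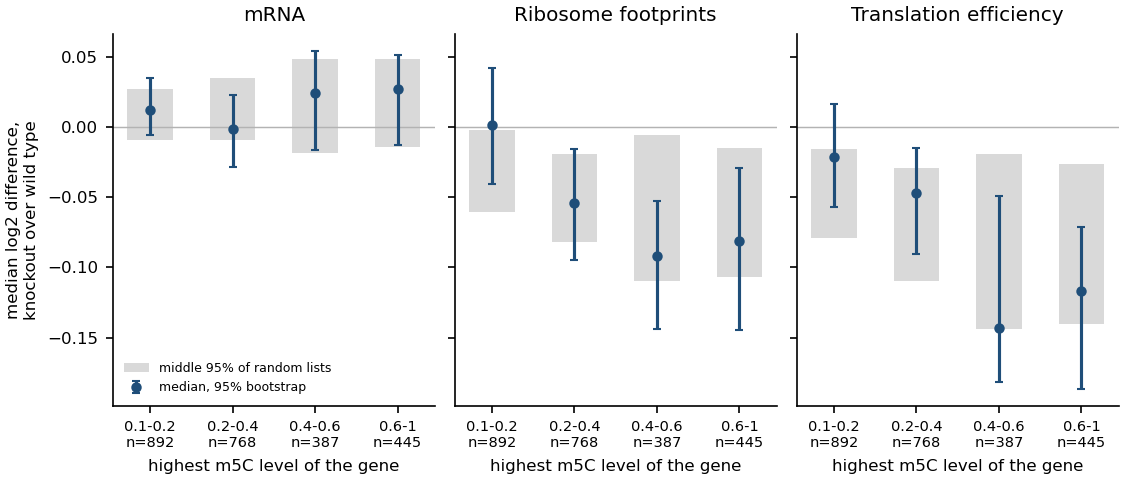
Median log2 difference between knockout and wild type (y axis) for genes grouped by their highest listed m5C level (x axis, fraction) in mRNA, ribosome footprints and translation efficiency. Points are medians with 95% bootstrap intervals over genes and grey bars hold the middle 95% of random lists matched on mRNA level; the translation efficiency medians run from -0.02 in the lowest group to -0.14 and -0.12 in the upper ones, and 3 other scalings, which move all groups alike, put the 2 lower groups above 0.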

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

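The trimmed mean scaling, the pseudocount of 1 and all alternatives for m5C level and coding length were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Of the values that answer a comparison, 57 counts stayed within 1.5 times the reported one and 9 did not. Of the correlations and differences, 42 stayed within their bootstrap interval and 2 did not. Another scaling moves all genes by 1 amount, and the 1.5-fold rule does not enter these correlations and differences. Neither can change them, so a part of the 42 was fixed beforehand and is no sign of stability. With at least 200 reads, footprints had 22 genes higher and 70 lower, translation efficiency had 41 higher, the rho of mRNA and footprint differences was 0.107, and that of translation efficiency between genotypes was 0.902; fewer genes entered. With the 1.5-fold rule, which admits smaller differences, mRNA had 171 higher and 161 lower, footprints 208 and 343, and translation efficiency 247 and 424. The median log2 differences of footprints and translation efficiency changed sign to 0.033 and 0.0017 with the total reads of the listed genes, to 0.013 and 0.0025 with median of ratios, and to 0.024 and 0.0044 with the trimmed mean. Those of genes with m5C levels from 0.2 to 0.4 changed sign to 0.025 and 0.013, to 0.0046 and 0.014, and to 0.016 and 0.016 under the same scalings. These 3 scalings raise every footprint difference by 1 amount, at most 0.08 on the log2 scale. Among the other values, single genes included, 613 stayed within their interval and 35 moved out of it. A part of the 613 was also fixed, such as the rho of coding length and footprint difference under another scaling. The 33 shares of higher genes among those called moved by at most 10 percentage points. No other value whose interval excluded 0 changed sign. The rho of m5C level and translation efficiency difference ran from -0.064 to -0.050. The fixed gene lists and the codon comparison were not run under any setting, nor was a check of the knockout, since it was not determined which identifier is the targeted gene. Footprint depth, with a median of 288 and 275 recovered reads per gene, limits what can be read for single genes below 2-fold. The first of these medians, that of wild type, is probably too high.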

Other observations

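The test against the mRNA libraries alone and the comparison of separate collections with buffering, were chosen after the results were seen, as were the sets of 40 and 11 deeply read genes. Genes lower in knockout footprints included some of the most deeply read ones. With at least 500 footprint reads on average, 40 genes were at least 2-fold lower in footprints and 11 at least 2-fold higher, out of 987 genes. The 40 lower genes had a median translation efficiency of 8.22 in wild type and 2.54 in the knockout, against 2.01 and 1.90 for all 987. The 11 higher genes went from 1.30 to 1.93. These steps restate the choice of genes by their footprints, and genes picked for being lower also tend to start high. The 40 lower genes were 1.91 times as long in the median as all 987, and the 11 higher ones 0.436 times.

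Footprint differences were also ordered by coding length. Of 5 equal groups, the shortest genes had a median log2 footprint difference of 0.09 (0.06 to 0.13), with 20 genes at least 2-fold higher and 15 lower. The longest, 7.34 times as long in the median, had -0.20 (-0.23 to -0.15), with 2 higher and 41 lower. Of 5 equal groups by mRNA level, the lowest had -0.17 in footprints and the highest 0.13. Other scalings move each of these medians by -0.01 to 0.08.

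Coding length and the footprint difference had a rho of -0.193 (-0.231 to -0.155) across 2465 genes, and -0.167 without genes 2-fold apart. Counting error of thinly covered genes would leave little trend among deeply read genes. Among 962 genes with at least 500 reads, rho was -0.299 (-0.357 to -0.239). Counting error favours neither library, so this test could hardly have pointed to it. Reads follow both length and value, so the read minimum keeps short genes mainly at high values. Mean mRNA value had a rho of 0.206 with the footprint difference, so the step from -0.193 to -0.299 has no reading of its own. Expression level may account for a part, since the rho was -0.113 (-0.151 to -0.072) with mRNA and footprint levels taken out. These levels come from single libraries, the footprint level from the same 2 as the difference, so the size of that part is not settled. A difference in digestion or fragment recovery between the 2 footprint libraries, or an effect of NSUN2 loss on long messages, may underlie any remainder. Neither was tested because genotype and library are the same split.

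Genes with higher m5C levels had lower translation efficiency differences, with a rho of -0.054. The mRNA libraries alone do not account for it, because m5C level had a rho of -0.0764 (-0.116 to -0.039) with footprints alone. Gene length and mRNA level are a candidate explanation: with both taken out the rho was -0.0118 (-0.053 to 0.025). An m5C-dependent change stays open, since the rho was 0.0448 (-0.026 to 0.113) in the shortest 822 genes, -0.046 in those of middle length and -0.076 (-0.146 to -0.005) in the longest. In lists matched on length and mRNA level, the medians from the lowest to the highest m5C group stood at percentiles 78.3, 79.9, 4.74 and 23.1.

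Genes at least 2-fold apart in mRNA were followed little by footprints. Signed by the mRNA difference, the median over 70 genes was 1.30 in mRNA and 0.147 in footprints. In 100 simulations with counting error and full following it was 1.25 to 1.42. The simulations rest on the recovered reads and leave out all other variation between single libraries. The 70 genes were picked by their mRNA difference, which such variation can enlarge, so only counting error is addressed. The footprint libraries were able to show large differences, since 11 of the 70 genes were at least 2-fold apart the same way in both. Ovaries collected separately for the 2 assays, with other shares of egg stages, or translation that offsets mRNA differences may each give the low rho of 0.150. These and other variation between single libraries cannot be told apart with 1 library per assay and genotype.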
